A study of Drosophila melanogaster with 6 samples.

How the data were processed

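Polyadenylated RNA of S2 cells grown at 25 degrees in medium with 10% serum was sequenced after 5 days of RNAi, per the labels' protocols. The submitters' processing notes name TopHat, Bowtie and DESeq2, without versions or roles. The genome build is not given in the sources used here. Positions in the files equalled those of the BDGP6 (dm6) annotation for 81 of 81 matched genes of the dKDM4A table and 458 of 461 of the HP1a table, so positions are given as the files list them. Each RNAi treatment had a table of its own with the same 2 GFP libraries.

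The signal columns hold counts per feature that the authors normalized by a size factor per library, per the file headers, separately in each table. Values in a column were whole multiples of the value of 1 read (100% of values within 0.1 reads), which gave size factors from 0.717 to 1.26. The GFP reads so recovered were equal in both tables for all 43 shared features. Too few low values were at hand to treat these reads as raw counts, so no count test was run. The log2 fold changes and their standard errors are those of the authors, per the file headers. They were smaller in size than log2 ratios of mean normalized counts. The median quotient was 1.03 and 1.05 in the dKDM4A and HP1a tables, and the highest 1.20 and 2.05. Folds here were computed from the normalized counts, so some lie well above those deposited. The score column is the authors' log2 fold change divided by its standard error. The p-values and adjusted p-values are the deposited ones, and only rows with an adjusted p below 0.05 were present. Benjamini-Hochberg ranks in those values had no gaps and gave 7533 and 8287 tested features. For HP1a, 4 deposited p-values were listed as 0 and were recomputed from the score. There was 1 row without values per table, which held the second name of a split gene and was left out. 1 gene symbol of the HP1a table stood under 2 identifiers.

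Replicate libraries differed by more than sampling noise in recovered reads, with a chi-square per degree of freedom between 12.7 and 61.0, so each was counted as 1 library. Group values are means ± SD of normalized counts. Limma 3.58.1 (R 4.3.3) was run on log2(normalized count + 1) within each table, with Benjamini-Hochberg adjustment over the listed rows and a minimum mean of 1, which removed no row. A fold on this scale understates changes of low features. All adjusted p-values attributed to limma come from that model. The planned single fit of all 6 libraries was not used, because the tables were normalized separately. For the difference between HP1a RNAi and the libraries labelled dKDM4A RNAi, log2 values of the shared features were centred on the GFP mean of their own table. On simulated negative binomial data for the 535 listed features of the HP1a comparison, with 200 changed, limma recovered 50.0% of 1.5-fold and 97.2% of 2-fold changes and called 3 of 335 unchanged features. For the 90 features of the dKDM4A comparison, with 30 changed, it recovered 100% at both sizes and called 1 of 60 unchanged features. The simulated features had a common dispersion and were not selected by an adjusted p. These rates therefore do not describe limma on the listed rows, which were selected.

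The 19 gene lists, the tests and the rule for named genes were fixed before the data were examined, unless stated otherwise. The rule takes both targets and the 10 largest increases and decreases per comparison by deposited log2 fold change. It adds up to 10 shared features with the largest smaller change, and up to 4 members per list with the smallest adjusted p. Set tests that need members outside the tables were replaced, as planned, by counts and Fisher's exact tests. List sizes count symbols, and some genes stand in a list under several symbols, which also overstates the expected number. The hypergeometric tests of list counts were not part of that plan. They treat every list member as tested, which overstates the expected number, and they take no account of expression level. A count adjusted over the list alone was not computed since unlisted members were not analysed here. The heterochromatic set comprised chromosomes 4 and Y, 2L beyond 22 Mb, 2R up to 5.4 Mb, 3L beyond 23 Mb, 3R up to 4.2 Mb and X beyond 22 Mb; these rounded boundaries were set after the files were seen. Overlap by chance was simulated in 1000 draws of unchanged groups. The alternatives were pseudocounts of 0.1 and 5, no filter, the replicate block, each library left out, an adjusted p below 0.01, an absolute log2 fold change of at least 1, a mean of at least 100, matching by symbol and a narrower heterochromatic set. Other scalings could not be tried on the listed rows alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.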

Results

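The series measured polyadenylated RNA by sequencing in Drosophila S2 cells, a line of embryonic origin with haemocyte-like properties. The cells were treated for 5 days with double-stranded RNA against GFP as the control, against dKDM4A or against HP1a. There were 6 libraries, 2 in each of 3 groups. dKDM4A is the gene Kdm4A, a demethylase of histone H3. HP1a is a protein that binds methylated histone H3 in heterochromatin. Each RNAi treatment was compared with the GFP control in a table of its own, and only features with an adjusted p below 0.05 in the authors' deposited table were at hand. A feature is a gene or a repeat consensus. The median listed feature of the dKDM4A table held between 2294.5 and 3362 reads per library, and that of the HP1a table between 745 and 1391. The total depth of the libraries is unknown, because features that did not pass were not analysed here. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

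The targeted genes were examined first, because they check the labels. Kdm4A (FBgn0033233, chromosome 2R, 7922775 to 7924988, minus strand) was higher, not lower, in the libraries labelled dKDM4A RNAi. Its normalized count was 843 ± 0.742 (SD, n = 2) in GFP RNAi and 2408 ± 378 (SD, n = 2) in the libraries labelled dKDM4A RNAi, a 2.86-fold increase. This was the largest increase of that comparison, and it goes against the label. Every direction given below for this comparison therefore refers to the libraries labelled dKDM4A RNAi. The HP1a gene (FBgn0003607, chromosome 2L, 8209626 to 8211122) was lower in HP1a RNAi, in the direction its label gives. It fell from 23735 ± 2506 (SD, n = 2) to 14269 ± 2030 (SD, n = 2), which left 60.1% of the control level.

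**Figure D1:**
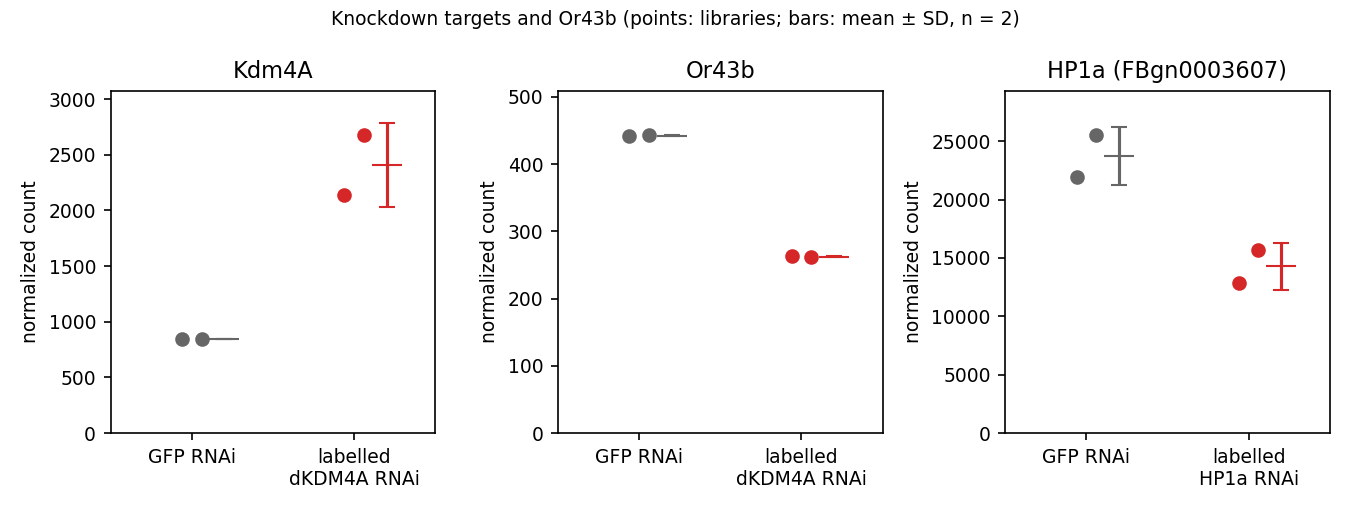
Normalized counts of Kdm4A, Or43b and the HP1a gene in each library (points), with the group mean and SD (bars, n = 2); the vertical axes start at 0. Kdm4A was 2.86-fold higher in the libraries labelled dKDM4A RNAi, while the HP1a gene stood at 60.1% of control in HP1a RNAi.

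The first comparison asked which transcripts differ between the libraries labelled dKDM4A RNAi and GFP RNAi. The changes were few and mostly small. Of 90 listed features 66 were higher and 24 lower, among 7533 features tested. After Kdm4A, the largest increases were in CG5697 (2.41-fold) and in Pxn, which encodes the extracellular matrix peroxidase peroxidasin (2.04-fold). Pxn rose from 138972 ± 27581 to 283413 ± 19453 normalized counts (SD, n = 2 each). The pigmentation gene e rose 1.84-fold, yellow-h 1.77-fold, CG34347 1.75-fold and daw, an activin-type ligand, 1.70-fold. The 5'-nucleotidase gene veil rose 1.67-fold, CG4611 1.67-fold and Pfk, the glycolytic phosphofructokinase, 1.59-fold. These increases were picked by the deposited log2 fold change. By normalized counts other genes came between them, such as CG12520 at 1.68-fold, which was named after its value was seen.

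The decreases in the libraries labelled dKDM4A RNAi were all less than 2-fold. Or43b, an odorant receptor gene, had the largest, from 442 ± 1.09 to 263 ± 1.04 normalized counts (SD, n = 2 each). It lies on chromosome 2R from 7920835 to 7922604, 170 bp beyond the 3' end of Kdm4A on the same strand. Its 3' part overlaps the opposite-strand gene Cul1 by 745 bp, so its reads cannot be assigned with certainty if counting ignored strand. piwi, which encodes an Argonaute protein of the piRNA pathway, fell from 9345 ± 230 to 5709 ± 72.8 (SD, n = 2 each), or 1.64-fold. Cyp4s3 was 1.61-fold lower and dmGlut 1.57-fold lower. AdamTS-A, CG12206, CG9705, Wunen-family gene wun2, Glg1 and the DNA repair nuclease gene Rrp1 were between 1.46-fold and 1.51-fold lower. The telomeric retrotransposons HETA and TAHRE, the only 2 repeats listed, were lower by 1.25-fold and 1.43-fold; they were named after their values were seen.

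Few members of the gene lists fixed in advance were listed in the libraries labelled dKDM4A RNAi. In all, 10 genes of those lists appeared. Haemocyte markers had 2 of 25 members listed, Pxn and NimC1 (1.29-fold), both higher. Glycolysis and lactate genes had 2 of 15 members listed, Pfk and ImpL3 (1.24-fold), both higher. The 15 count ImpL3 also under its current symbol Ldh. ImpL3, the lactate dehydrogenase gene, was also the 1 listed member of the ecdysone list. Single members were listed for immune genes (Tep1, 1.63-fold higher), cytoskeleton and adhesion (Fas1, 1.56-fold higher), ribosomal proteins (RpL18, 1.42-fold higher), chromosome 4 (yellow-h, higher), the piRNA pathway (piwi, lower) and heterochromatin proteins (Kdm4A itself). The other 10 lists had 0 members listed. Against the expectation from all 7533 tested features, the lowest enrichment p was 0.0134 for glycolysis, and none of the 19 lists passed adjustment (one-sided hypergeometric test, lowest adjusted p = 0.255).

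Limma on log2(normalized count + 1), run on the 90 listed rows alone, called all 90 at an adjusted p below 0.05. These rows had already been selected on the same libraries, so that count is not independent evidence. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333. Of the listed features 73.3% were higher (95% exact binomial interval 63.0 to 82.1, two-sided p = 1.1e-05 against an equal split, across features that are not independent replicates).

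The second comparison asked which transcripts change after HP1a RNAi. The response was broader, with 346 features higher and 189 lower among 8287 tested. The 10 largest increases by log2 fold change in the authors' deposited table were in 5 repeats and 5 genes. The retrotransposon ACCORD2_I rose from 122 ± 32.4 to 6742 ± 1271 normalized counts (SD, n = 2 each), or 55.2-fold. G_DM, a non-LTR element, rose 15.7-fold, ACCORD2_LTR 16.2-fold, G6_DM 8.76-fold and GYPSY10_I 8.21-fold. Among genes, CG18605 on chromosome 2R rose from 111 ± 12.7 to 1756 ± 114 (SD, n = 2 each), or 15.9-fold. CG3251 rose 17.5-fold, modSP, a serine protease of Toll signalling, 10.5-fold, and tio, a zinc finger gene, 10.2-fold. l(3)mbn rose 38.8-fold from a control level of only 3.04 ± 2.32 normalized counts (SD, n = 2), so its fold is imprecise.

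The largest decreases in HP1a RNAi were in CG9521, from 342 ± 103 to 48.2 ± 3.62 normalized counts (SD, n = 2 each), and in the serpin gene Spn88Eb, which was 3.58-fold lower. CG30440 was 3.42-fold lower, CG11634 3.16-fold, CG31600 3.13-fold, CG33120 3.11-fold, CG10834 2.90-fold and CG14990 2.77-fold. From chromosome 4, Rfabg, which encodes an apolipoprotein precursor, was 3.15-fold lower and bt, which encodes the muscle protein projectin, 2.97-fold lower. CG31600 and CG11634 are close neighbours on chromosome 2L, between 21914269 and 21920324.

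The repeats listed for HP1a RNAi were mostly higher, and repeats that did not pass were not analysed here. Of 46 listed repeat features, 41 were higher and 5 lower, against 305 genes higher and 184 lower (Fisher's exact test, two-sided, p = 0.000153). The comparison of repeats with genes was chosen after the values were seen. LTR retrotransposons made up 28 of these features, of which 26 were higher, and non-LTR elements outside the telomeres 14, of which 13 were higher. R1_DM, which inserts in ribosomal DNA, rose from 761 ± 80.6 to 3618 ± 128 (SD, n = 2 each). The 5 lower repeats were HETA (1.24-fold), TAHRE (1.39-fold), IDEFIX_I (1.78-fold), IDEFIX_LTR (2.06-fold) and IVK_DM (1.35-fold). These 6 repeats were named after their values were seen. Internal and LTR parts of one element are separate rows, and the 46 rows stand for 39 families. How reads with several matches were counted is not given in the sources used here, so values of related repeats may share reads.

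**Figure D2:**
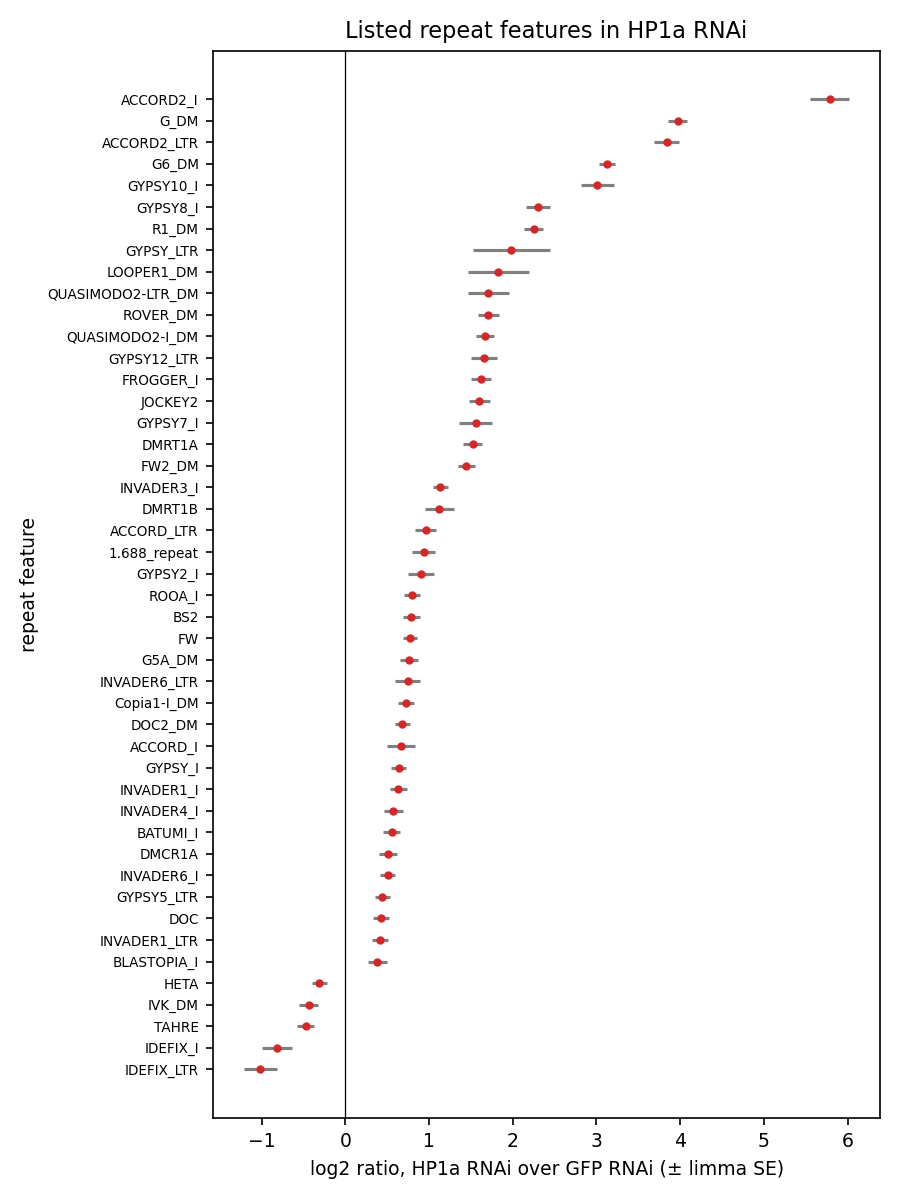
Log2 ratio of HP1a RNAi over GFP RNAi (horizontal axis, on the log2(normalized count + 1) scale) for each listed repeat feature (vertical axis), with the limma standard error as bars. Of the 46 listed repeats, 41 lie above 0, with ACCORD2_I highest at 5.79.

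The listed genes of chromosome 4, a small chromosome rich in heterochromatin, were mostly lower in HP1a RNAi. Of 118 annotated genes there 16 were listed, and 13 of the 16 were lower, or 81.2%, compared with 36.3% of the other positioned genes (Fisher's exact test, two-sided, p = 0.000401). Of the 52 chromosome 4 genes fixed in advance 11 were listed, 9 lower and 2 higher. Sox102F was 2.17-fold lower and Cadps, a regulator of vesicle release, 2.60-fold lower, while the higher genes dati (5.80-fold) and ey (2.01-fold) were named after their values were seen. If all 52 had been tested, 3.36 would be expected by chance (one-sided hypergeometric test, adjusted p = 0.00743 over 19 lists). The wider heterochromatic set, which adds the heterochromatic parts of the arms, had 39 listed genes, of which 61.5% were lower (Fisher's exact test, p = 0.00185). Without chromosomes 4 and Y, 47.8% of 23 genes were lower, and this did not differ from the other genes past the threshold (Fisher's exact test, p = 0.379). No shifted boundary was tried, although listed genes such as CG31600, CG11634 and CG30440 lay just outside the rounded ones. The list of pericentromeric genes had 2 of 29 members listed, Cht3 (1.88-fold higher) and AGO3 (1.62-fold lower).

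**Figure D3:**
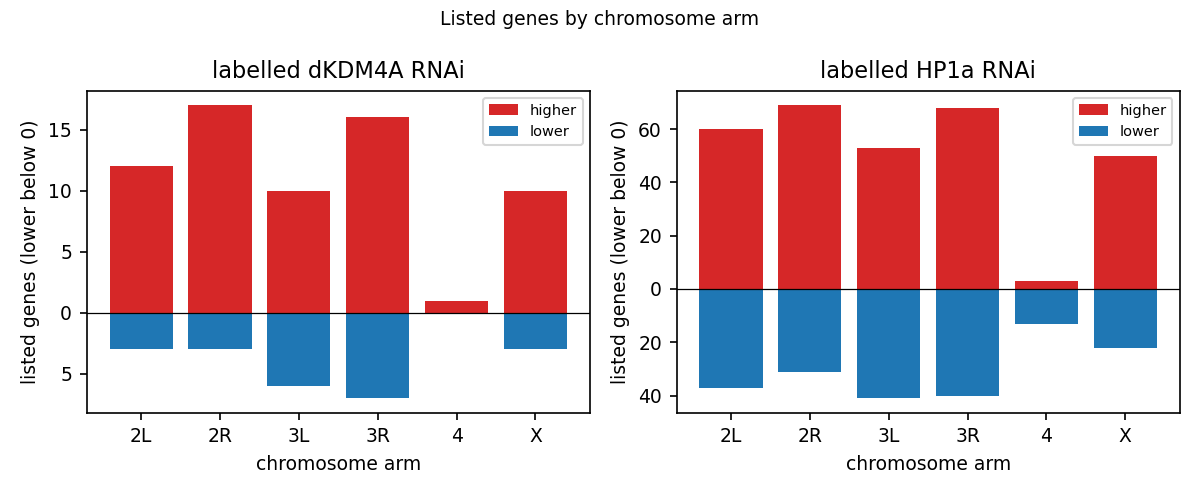
Number of listed genes per chromosome arm that were higher (above the line) or lower (below the line) than GFP RNAi, for each comparison; the vertical scales differ. On chromosome 4, 13 of 16 listed genes were lower in HP1a RNAi.

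Of the centromere and chromosome segregation list, 5 of 37 members were listed in HP1a RNAi and all 5 were lower (Fisher's exact test of direction against the rest of the table, adjusted p = 0.0399). The kinase gene aurB was 1.31-fold lower, the kinetochore genes Spc105R and Cenp-C 1.27-fold and 1.26-fold, and cmet 1.17-fold. The changes were small, and under limma Spc105R, Cenp-C and cmet did not pass when any 1 of the 4 libraries was left out (adjusted p from 0.0515 to 0.0929, from 0.0569 to 0.107 and from 0.117 to 0.192). With the replicate number as a block, cmet no longer passed (limma adjusted p = 0.054). The limma call of aurB was lost without GFP RNAi replicate 2 or HP1a RNAi replicate 1 (adjusted p up to 0.0708). The number listed did not exceed the expected 2.39 past the threshold (hypergeometric test, adjusted p = 0.414). The cell cycle list had 1 member, aurB again.

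Markers of haemocytes and of the germline appeared among the higher genes in HP1a RNAi. All 5 listed haemocyte markers, of 25, were higher, among them Pxn (2.26-fold), drpr (1.46-fold), NimB1 (1.38-fold) and lz (from 14.2 ± 2.38 to 59.7 ± 35.4 normalized counts, SD, n = 2 each). All 3 listed germline markers, of 30, were higher, with vas at 5.06-fold, osk at 2.63-fold and zpg at 1.34-fold. The folds of vas and osk are imprecise, because their mean normalized counts were only 62.2 and 76.5. Their deposited log2 fold changes were 1.76 and 1.14. Of 31 piRNA pathway genes 4 were listed, with vas, aub (1.34-fold) and tej (1.32-fold) higher and AGO3 lower. Neither haemocyte nor germline markers passed adjustment for their number (hypergeometric adjusted p = 0.126 and 0.829) or for their direction against the rest of the table (Fisher's exact test, adjusted p = 0.501 and 0.926). The muscle list had bt alone, and neuronal markers had 0 members listed.

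The remaining lists held few members in HP1a RNAi. Ribosomal protein genes had 8 of 92 listed, all higher, including RpL18 (1.48-fold), RpS15Ab (1.29-fold), RpS25 (1.25-fold) and RpL10Ab (1.18-fold), with an adjusted p of 0.277 for direction by Fisher's exact test. RpL10Ab did not pass limma with the replicate number as a block (adjusted p = 0.0516). Cytoskeleton and adhesion genes had 6 of 28, with Fas1 (1.98-fold), Nrg (1.39-fold) and betaTub60D (1.35-fold) higher and tutl (2.75-fold) lower, and an adjusted p of 0.0743 for their number. The DNA damage genes mus308 and p53 were 1.45-fold and 1.28-fold higher. Hsp23 was 2.01-fold higher, Tep1 1.86-fold and Pfk 1.84-fold. Among heterochromatin proteins only the HP1a gene and Lam, the lamin gene (1.23-fold lower), were listed. JAK-STAT, ecdysone and histone genes had 0 members listed.

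For HP1a RNAi, limma on log2(normalized count + 1) called 525 of the 535 listed rows, which again had been selected on the same libraries. Leaving out HP1a RNAi replicate 2 lowered that number to 334. Besides the centromere genes, the limma calls of AGO3, Lam, RpL10Ab, RpS15Ab, RpS25, betaTub60D, p53, tej and veil were lost when certain single libraries were left out, with the highest adjusted p between 0.0521 (veil) and 0.150 (RpL10Ab). Of the 535 features 64.7% were higher (95% exact binomial interval 60.5 to 68.7, two-sided p = 1.1e-11). That split did not differ past the threshold from the split in the libraries labelled dKDM4A RNAi (Fisher's exact test, two-sided, p = 0.119). The test treats the lists as independent, although 43 features are in both and the GFP libraries are shared, so its p is only descriptive.

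The third comparison set both lists side by side. There were 43 features in both, 41 genes and the repeats HETA and TAHRE, and all 43 had changed in the same direction, 35 higher and 8 lower. They made up 47.8% of the features listed for the libraries labelled dKDM4A RNAi and 8.04% of those listed for HP1a RNAi. Ranked by the smaller of their 2 changes, the first shared genes were Pxn, CG5697, Pfk, CG4611, Tep1, Fas1, CG33181, Cyp6a14, CG11825 and veil, and these 10 were higher in both. That ranking leaves out genes whose change was large in HP1a RNAi and smaller in the other comparison, such as CG34331, which was 3.03-fold higher in HP1a RNAi and 1.47-fold higher in the libraries labelled dKDM4A RNAi, and was named after its values were seen. CG33181 rose 1.59-fold in the libraries labelled dKDM4A RNAi and 2.29-fold in HP1a RNAi, and CG11825 rose 1.56-fold and 2.14-fold. Independent lists would share 3.03 higher and 0.602 lower features. Both comparisons used the same 2 GFP libraries, and simulated unchanged groups against shared controls shared 0.493 features on average, of which all 0.493 agreed in direction. Agreement in direction is therefore what shared controls give by themselves, and no test of it is reported. The controls are too few to split, so part or all of the excess may come from the shared controls.

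**Figure D4:**
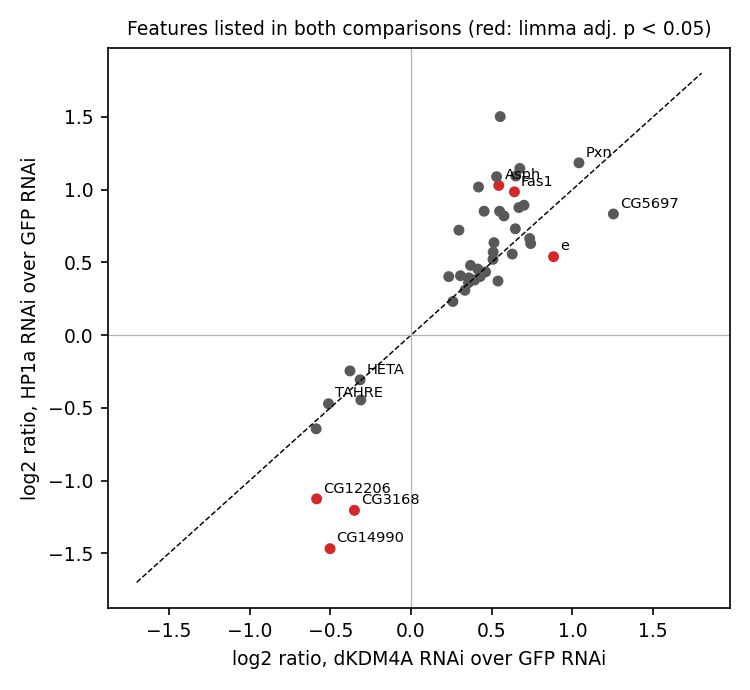
Log2 ratio over GFP RNAi in HP1a RNAi (vertical axis) against that in the libraries labelled dKDM4A RNAi (horizontal axis) for the 43 features in both tables, on the log2(normalized count + 1) scale; the dashed line marks equal ratios. All 43 lie in the lower left or upper right, and red points mark the 6 features whose ratios differed by limma.

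Only for these 43 features could HP1a RNAi be compared with the libraries labelled dKDM4A RNAi, and each table was first centred on its own GFP mean because the tables were normalized separately. By limma with Benjamini-Hochberg adjustment over 43 features, 6 differed. CG14990, CG3168 and CG12206 fell further in HP1a RNAi, with log2 differences of -0.97, -0.85 and -0.54 (adjusted p = 0.0046, 0.0206 and 0.017). Asph and Fas1 rose further in HP1a RNAi, by 0.48 and 0.34 (adjusted p = 0.017 and 0.0279), and e rose less, with a difference of -0.34 (adjusted p = 0.0385). CG3168 and Asph were named after their values were seen. The number and its balance depended on the fit and on single libraries. With the replicate number as a block limma called 0 features (9 at an unadjusted p below 0.05). Without either of the libraries labelled dKDM4A RNAi it also called 0 (6 at an unadjusted p below 0.05). All libraries gave 2 positive and 4 negative log2 differences, while 14 positive and 7 negative were called without HP1a RNAi replicate 1, and 10 positive and 5 negative without HP1a RNAi replicate 2.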

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

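The alternatives were fixed before the data were examined, except those for repeats. Pseudocounts and the filter left 90, 525 or 526 and 6 limma calls. None of the 28 and 58 features that the rule named (dKDM4A, HP1a) changed sign. This was fixed in advance, because in every listed feature both RNAi libraries lay on the same side of both GFP libraries. With an absolute log2 fold change of at least 1, the lists shrank to 2 (labelled dKDM4A, 100% higher, exact binomial p = 0.5) and 96 features (HP1a), the overlap to 0 and the fixed-list members to 1 and 10. With an adjusted p below 0.01, 344 HP1a features and an overlap of 24 were left. These follow from stricter thresholds. Without chromosomes 4 and Y, the heterochromatic share of lower genes was 47.8% (11 lower, 12 higher, Fisher's exact p = 0.379), with fewer genes. Leaving out single libraries gave 84 to 90 limma calls for the libraries labelled dKDM4A, 334 to 383 for HP1a and 0 to 21 for their difference, whose balance turned from 2 positive and 4 negative to 14 and 7 or 10 and 5 without an HP1a library; the cause was not tested. Of 58 features named for HP1a, 13 lost the limma call without at least 1 library and 6 without any 1 of the 4: Cenp-C, Lam, RpL10Ab, RpS25, Spc105R and cmet. AGO3, RpS15Ab, p53 and tej lost it without 3, aurB without 2, and betaTub60D and veil without 1. A lone library was assumed to vary like the other group. The spread in such fits is largely pooled over rows that were selected on the same libraries. Some adjusted p-values of the dKDM4A comparison, such as that of Kdm4A, even fell when a library was left out. The number of calls kept therefore does not show robustness and cannot be compared between the 2 tables. Libraries share only a replicate number; with it as a block, limma called 90, 513 and 0 features and lost 2 of those 58, cmet and RpL10Ab, and the deviations of same-numbered libraries correlated at 0.276 and 0.237 across features. Count tools were not run, because the files hold no raw counts. Low control counts limit folds such as those of l(3)mbn, vas, osk, dati and CG10178, whose deposited fold changes are smaller than those given here.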

Other observations

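The tests of gene families and of Kdm4A and its neighbour were chosen after the values were seen, while the transposon distance and the simulated overlap were specified before their results. In the libraries labelled dKDM4A RNAi, genes of haem synthesis were listed more often than expected. Updo (1.43-fold), Alas (1.41-fold) and FeCH (1.20-fold) were higher, 3 of 7 family members against 0.0836 expected (one-sided hypergeometric adjusted p = 0.000279 over 5 families). Of 35 aminoacyl-tRNA synthetase genes 4 were higher, Aats-asn (1.35-fold), Aats-ile (1.28-fold), MetRS (1.25-fold) and Aats-his (1.23-fold), with a hypergeometric adjusted p of 0.00125. These 4 had high mean normalized counts, from 8089 to 27892, where small changes pass more easily. The test took no account of expression level. Of 87 cytochrome P450 genes 6 were listed, 5 higher and Cyp4s3 lower (adjusted p = 0.00125). UDP-glycosyltransferase and glutathione S-transferase genes had 0 members listed. Families picked from the listed genes are favoured by such a test.

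In HP1a RNAi, 9 cytochrome P450 genes were listed and all were higher, with Cyp4p1 at 2.55-fold and Cyp4ad1 at 2.14-fold, but neither their number (adjusted p = 0.179) nor their direction (Fisher's exact test, adjusted p = 0.152) passed adjustment. Of 35 UDP-glycosyltransferase genes 7 were listed, 6 higher, such as CG10178 (3.16-fold) and Ugt36Ba (2.14-fold), and Ugt86Dj lower by 1.72-fold (adjusted p = 0.031). These genes lie in clusters of similar copies and may share reads, which was not tested; the hypergeometric p for their number before adjustment was 0.0062. All 4 listed glutathione S-transferase genes were higher (adjusted p = 0.234). Of haem synthesis genes 2 of 7 were listed and of aminoacyl-tRNA synthetase genes 1 of 35, all higher (hypergeometric adjusted p = 0.176 and 0.904).

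Kdm4A was higher in the libraries meant to lack it, and Or43b, its neighbour 170 bp downstream, had the largest decrease. A candidate explanation is that reads of the transfected double-stranded RNA were counted as Kdm4A. The HP1a gene was lower in HP1a RNAi (log2 ratio -0.74), with its own double-stranded RNA. This cannot decide the question, because its control level was far above that of Kdm4A and could hide such reads. No values by position within Kdm4A were at hand. Or43b reads (log2 ratio -0.75) may come from transcripts that run on from Kdm4A; this needs such transcripts to fall while the reads counted for Kdm4A rose, and nothing here shows reads between both genes. A swap of the GFP and dKDM4A labels would make Kdm4A higher in HP1a RNAi as well, where it had 0 rows in a list that held 73 higher features within 2 times its control level, with folds from 1.22. That absence counts against the swap. The 47 of 90 features not in the HP1a list do not decide it. Small changes can miss the listing threshold. However, piwi (1.64-fold lower) and daw (1.70-fold higher) were among the 47, with deposited adjusted p-values of 1.9e-20 and 2.2e-07. A swap would need HP1a RNAi to have changed such genes as well, which is not known here. A swap would give the common direction of all 43 shared features, but shared controls give it without a swap, so it does not bear on the question. The swap, the other explanations and a true increase of Kdm4A cannot be told apart.

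All 43 shared features changed the same way, as features shared through common controls also would. The shared GFP libraries alone, with no effect of either treatment, gave at most 4 shared features in 1000 simulated draws. Those draws assumed independent features and correctly scaled scores, and could not hold a deviation common to both GFP libraries. They answer only for noise of that size and do not decide whether the controls account for the number. A response common to both treatments, the shared controls with or without real effects, or the label swap weighed above may account for it. The swap would also give a common direction, and the 47 of 90 features that were not shared do not decide it, for the reasons given above.

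The hypothesis that genes near transposable elements rise after HP1a RNAi was tested on genes with a position. An annotated element lay within 5 kb of 31.4% of 303 higher genes and of 33.7% of 184 lower genes. The difference was -2.34 percentage points (95% Newcombe interval -11.0 to 6.08; Fisher's exact test, two-sided, p = 0.618). The data do not show the predicted excess, and the interval still allows one of up to 6.08 points. The test did not take location into account. On chromosome 4, 13 of 16 listed genes were lower, so location could mask an excess elsewhere. Insertions particular to S2 cells are missing from the annotation, so the hypothesis may hold for those.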
